A study of Mus musculus with 6 samples.

How the data were processed

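Each of the 6 deposited files holds 1 value per gene for 1 lane of 1 library of polyadenylated RNA, in FPKM (fragments scaled to transcript length and to the mapped fragments of a file) as computed by the authors. The labels name the dose of SHP099 of each file, and the names of the files of a dose are alike up to the lane, 6 or 7. A dose was therefore read as 1 library sequenced in 2 lanes, and lanes were treated as repeat runs, not as replicates. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8; the tool that made the FPKM and any scaling between files are not stated. Of 53460 gene identifiers in the files, 53356 are in an Ensembl-based annotation of the later build GRCm38, so the gene models are later than the build named and no positions are given. Whether the FPKM of Pdgfra and Pdgfa include the introduced genes cannot be told from these values, since the species and form of those constructs are not given.

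All files list the same 53460 genes. Values of gene symbols with several entries (110 of 53346 symbols, of which 27 were compared) were summed. Means over the lanes were taken on the scale log2(FPKM + 1), and FPKM levels are arithmetic means. The genes compared are the 12567 with a mean of at least 1 FPKM in at least 1 of the 3 doses. FPKM were used as deposited. Their sum per file was 643175 and 643707 at 0 µM, 953134 and 567051 at 5 µM and 553504 and 552800 at 10 µM; the excess at 5 µM comes from the small nucleolar RNA gene Snora62, listed at 385860 FPKM in the lane 6 file of 5 µM and at 0 elsewhere.

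Depth was recovered from the values. For genes with 1 annotated transcript of 1500 to 6000 bases, the number of mapped fragments was fitted so that the FPKM of genes under 10 fragments became whole numbers, with 240 bases subtracted from the length. Between 97.6% and 98.4% of 1270 to 1404 such genes per file came out whole within 0.1, where chance gives 20%. The counting error of a 2 kb transcript at 1 FPKM is then 10.3% to 12.7% per lane, and 3 fragments correspond to 0.0318 to 0.0487 FPKM. These cover counting error only. Between the lanes of a library, the chi-square per degree of freedom of these fragments was 1.96 at 0 µM, 1.66 at 5 µM and 1.95 at 10 µM, which is above counting error alone; between 0 and 10 µM it was 24.8 to 26.1.

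The size rule, the 34 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. With 1 library per dose there is no test between doses. A gene counts as higher or lower when the mean log2 values differ by at least 1.5-fold and all 4 differences between a lane of one dose and a lane of the other have the same sign. The median log2 fold of each list with at least 5 measured members was placed among 10000 random lists of the same size, matched in 20 bins of mean expression. The percentile describes these libraries, as genes are not replicates. Overlap was set beside the count of independent calls. In 100 simulations of unchanged libraries with lane noise no gene was shared, but these hold no variation between cultures and so are no measure of chance for the overlap. The procedure was tested on simulated data: of 50 genes given a true change, 17 were called at 1.5-fold and all at 2-fold and above, and no unchanged gene was called. The simulated noise was set from the median lane difference and holds no variation between cultures. Real lane differences had a standard deviation of 0.211 to 0.258 on the log2 scale. The absence of false calls and the full recovery therefore do not carry over to these data.

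Named genes are 10 fixed genes (Ptpn11, Pdgfra, Pdgfa, Cdkn2a, Dusp6, Spry4, Etv5, Egr1, Ccnd1 and Myc), the 10 highest and 10 lowest called genes for 10 against 0 µM and the 5 highest and 5 lowest for each other comparison among genes with at least 5 FPKM in the higher dose, leaving out unnamed gene models, and up to 4 members per list with the largest folds at 10 against 0 µM. Other genes are said to be chosen after their values were seen.

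The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, a trimmed mean scaling (30% of ratios and 5% of levels trimmed), scaling to the same sum, scaling to a median log2 fold of 0, each lane file left out, each lane alone, a 2-fold rule, other ways of joining entries of a symbol, random lists without matching, and means in place of medians. limma 3.58.1 in R 4.3.3 was run over the 6 lane files with trend and robust fitting, with and without the lane as a block, at an adjusted p of 0.05 and 1.5-fold; it measures lane noise only and compares libraries. Chosen after seeing the data were protein-coding genes alone, scaling to the same sum without Snora62, and random lists of protein-coding genes matched in 10 bins of expression, 5 of transcript length and 3 of GC content. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.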

Results

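Polyadenylated RNA was sequenced from mouse glioma cells grown with 0, 5 or 10 µM SHP099, an allosteric inhibitor of SHP-2, the tyrosine phosphatase that Ptpn11 encodes and that relays receptor tyrosine kinase signals to RAS and ERK. Per the labels, the cells are astrocytes that lack Ink4a/Arf and carry PDGFRa and PDGF-A. The labels do not give the length of treatment. Each dose had 1 library, sequenced in lanes 6 and 7, so the 6 files hold 3 libraries and each dose has n = 1. Values are FPKM (fragments scaled to transcript length and to the mapped fragments of a file) averaged over the lanes. Fragments recovered from the steps between low FPKM values came to 46880000 and 47120000 for the lanes of the 0 µM library, 37900000 and 38580000 at 5 µM and 30820000 in each lane at 10 µM. At 1 FPKM, a transcript of 2 kb then has between 61.6 and 94.2 fragments per lane.

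The lanes show the error of sequencing, not the variation between cultures, so no p-value between doses can be given. Among 12567 genes with a mean of at least 1 FPKM in at least 1 dose, the lanes of 1 library differed by a median of 0.05 to 0.06 on the log2 scale. Between doses the median difference was 0.37 for 5 against 0 µM, 0.41 for 10 against 0 µM and 0.10 for 10 against 5 µM. A gene is called higher or lower here when its mean differs by at least 1.5-fold on log2(FPKM + 1) and all 4 lane-to-lane differences have the same sign. The lanes of 1 library differed by at least 1.5-fold for 119 genes at 0 µM, 149 at 5 µM and 211 at 10 µM. The ranges after a fold are those over the 4 pairs of lanes. A gene list stands apart when its median log2 fold lies within the outer 2.5% at either end of 10000 random lists matched on expression.

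The comparison of 10 with 0 µM asks which genes differ in glioma cells when SHP-2 is inhibited. Genes that ERK activity is known to induce were lower, and so were nearly all genes of DNA replication and mitosis and most genes of ribosome production and glycolysis. Fosl1, an AP-1 transcription factor, fell from 62.1 to 2.06 FPKM (log2 fold −4.37, −4.42 to −4.31), and the proliferation marker Mki67 fell from 94.6 to 5.67 FPKM (−3.84, −3.87 to −3.81). Genes of the extracellular matrix and of lysosomes were higher: Fmod, which encodes the collagen-binding proteoglycan fibromodulin, rose from 2.12 to 65.6 FPKM (4.42, 4.39 to 4.44), and Hexa, a subunit of lysosomal beta-hexosaminidase, rose from 36.7 to 180.8 FPKM. In all, 1978 genes were higher and 2396 lower, 34.8% of the genes compared. At 2-fold the counts were 733 and 995.

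The target and the receptor pathway itself differed little in RNA level. Ptpn11 (ENSMUSG00000043733) was at 59.0, 58.4 and 57.7 FPKM at 0, 5 and 10 µM. Pdgfra, the PDGF receptor, was at 74.8, 81.7 and 73.8 FPKM, and its ligand Pdgfa at 21.2, 20.7 and 21.3 FPKM. Of 33 measured genes for components from the PDGF receptor and SHP-2 to RAS, 5 were higher at 10 µM and 3 lower, with a median log2 fold of 0.04 (percentile 85.1). Among them Braf, a RAF kinase, rose by 0.87 and Pik3r1, a regulatory subunit of PI3 kinase, by 0.73, while Nras (−0.76) and Rasa1 (−0.74), which encodes a RAS GTPase-activating protein, fell. With each file scaled to the same sum, Nras (−0.55) and Rasa1 (−0.53) were no longer called.

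Genes that report ERK activity fell at 10 µM. Of 21 measured, 15 were lower and 1 higher, with a median log2 fold of −0.91 (percentile 0). The ETS transcription factors Etv4 (−3.82), Etv5 (−2.01) and Etv1 (−1.73) fell. So did the feedback inhibitors Dusp6, an ERK phosphatase (−1.02), and Spry4, a Sprouty protein (−1.11), the immediate early gene Egr1 (−0.91) and the cyclin D1 gene Ccnd1, from 238.0 to 81.8 FPKM (−1.53). With a pseudocount of 5 FPKM, Spry4 (−0.45) was no longer called. A separate list of 23 immediate early genes had 9 lower and 6 higher members and a median of −0.36 (percentile 1.92). The transcription factor genes Klf10 (−2.18) and Egr3 (−2.06) fell, whereas the antiproliferative gene Btg2 (1.64) and the stress-induced factor Atf3 (1.60) rose. This list no longer stood apart when genes needed 5 FPKM (percentile 34.8) or when the mean over members was used (11.7). Nor did it stand apart without the lane 6 file of 0 µM (3.04) or of 10 µM (2.67), in the lane 7 files alone (3.33), among protein-coding genes (2.65) or against lists matched on length and GC content (2.53). For ligands and receptors of other tyrosine kinases, 8 of 26 rose and 8 fell, with a median of −0.09 (percentile 35.6). The EGF receptor ligands Areg (−2.64) and Ereg (−1.58) fell, and Fgfr3, an FGF receptor (1.53), and Igf1, insulin-like growth factor 1 (1.48), rose.

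Cell-cycle genes had the lowest medians of all lists. All 38 genes of G2 and M phase were lower at 10 µM, with a median log2 fold of −3.02 (−3.10 to −2.98 over the lane pairs, percentile 0). Examples are Cenpa, the centromeric histone H3 variant (−3.73), the mitotic kinase Aurkb (−3.64) and Ccnb1, cyclin B1 (−3.57). Of 36 genes of S phase and DNA replication, 35 were lower and E2f1 alone was not called (−0.39), with a median of −2.26 (percentile 0). Mcm5, a subunit of the replicative helicase, fell from 199.1 to 14.2 FPKM (−3.72). Uhrf1, a maintenance factor of DNA methylation (−3.64), Cdc6, which loads the helicase (−3.42), and the thymidine kinase Tk1 (−3.38) fell too. Pclaf, a PCNA-binding factor outside these lists, fell by 3.84. E2f1 is named here after its value was seen, as the exception.

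Genes of cell-cycle arrest and of the p53 response moved in both directions. Of 25 measured, 8 were higher and 4 lower, with a median of 0.13 (percentile 93.5). The list stood apart as higher when genes needed 5 FPKM (98.5) and by the mean over members (98.9). Trp53inp1, a p53 target (2.14), the CDK4 and CDK6 inhibitor Cdkn2b (1.39) and the stress gene Sesn2 (1.21) rose, while the CDK inhibitor Cdkn2d fell (−1.14). Cdkn2a, the Ink4a/Arf gene that the labels give as deleted, was listed at 535.7, 822.6 and 802.7 FPKM. It was called higher at 5 µM (0.62), but not with equal sums, which Snora62 distorts (0.43). At 10 µM it was not called (0.58). Other scalings gave 0.65 to 0.80 there, and the fold without the lane 7 file of 0 µM was 0.61, all called. A value per gene cannot show which part of Cdkn2a the fragments came from. Of 20 apoptosis regulators, 3 rose and 2 fell, with a median of 0.00 and a mean of 0.05 (percentile 63.9). The BH3-only genes Bmf (1.78) and Bid (1.03) rose, and the BCL2 family gene Bok fell from 37.7 to 18.3 FPKM.

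Genes for making ribosomes were lower. Of 29 genes of MYC and ribosome biogenesis, 25 fell and Mxd4, a MYC antagonist chosen after its value was seen, rose by 1.60. The list had a median of −1.30 (percentile 0). Myc fell from 101.8 to 37.3 FPKM (−1.42). Nop56 (−1.90) and Fbl (−1.68), both of the box C/D ribonucleoprotein, the nucleolar gene Nolc1 (−1.62) and Cad, the enzyme that starts pyrimidine synthesis (−1.71), fell. Of 40 cytosolic ribosomal protein genes, 38 fell and none rose, with a median of −0.97 (percentile 0). Rpl3 (−1.42), Rps2 (−1.34), Rpl18 (−1.28) and Rps23 (−1.26) fell most. The summed FPKM of these 40 genes was 57549 at 0 µM and 29932 at 10 µM. The share of FPKM from mitochondrial genes was 4.85% and 4.92% in the lanes at 0 µM, 4.22% and 7.10% at 5 µM (7.10% in both with Snora62 left out) and 7.99% and 8.18% at 10 µM.

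**Figure D1:**
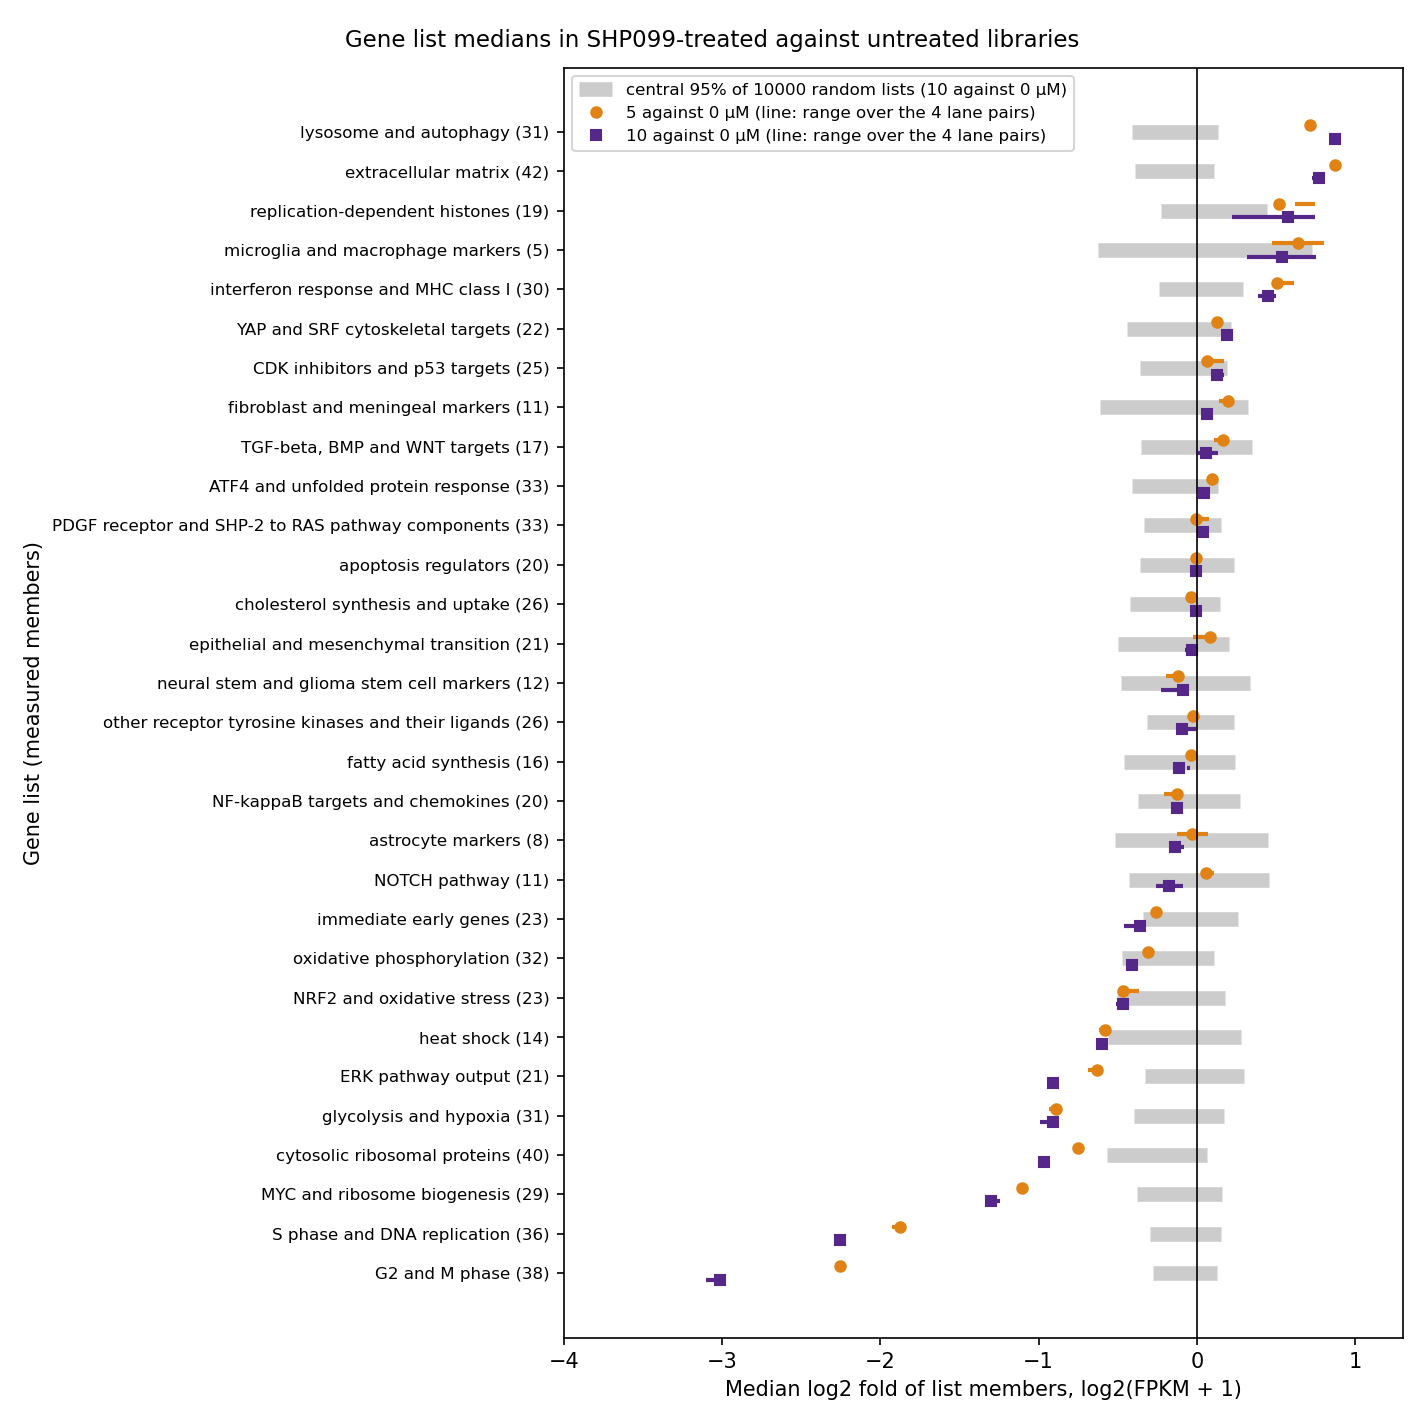
Median log2 fold of the measured members of each gene list, on log2(FPKM + 1), for 5 against 0 µM (circles) and 10 against 0 µM (squares). Coloured lines give the range over the 4 lane pairs, grey bars the central 95% of medians of 10000 random lists for 10 against 0 µM, and the number of measured members follows each list's name. The G2 and M phase list lies lowest, at −3.02 for 10 µM, and the lysosome list highest for 10 µM, at 0.87.

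Of 31 genes of glycolysis and hypoxia, 19 fell and 2 rose, with a median of −0.91 (percentile 0). The lactate exporter Slc16a3 (−2.70), the lactate dehydrogenase Ldha (−2.16), the hypoxia-induced Ankrd37 (−2.41) and the enolase Eno1 (−1.93) fell. Of 32 nuclear genes of oxidative phosphorylation, 9 fell and none rose, with a median of −0.41 that did not stand apart (percentile 6.42). Against random lists not matched on expression it did stand apart (0.19). Those named by rule, Cycs (−0.99), Uqcrc1 (−0.83), Atp5a1 (−0.79) and Cyc1 (−0.78), fell; Cycs encodes cytochrome c. With each file scaled to the same sum, Atp5a1 (−0.57), Cyc1 (−0.57) and the cholesterol gene Acat2 (−0.54) were no longer called. Of 26 genes of cholesterol synthesis, 4 fell and 2 rose, with a median of −0.01 (percentile 81.0). Lbr, a sterol reductase of the nuclear envelope (−1.75), Stard4, a sterol transporter (−0.89), and Acat2 (−0.75) fell, and Hsd17b7 rose (0.75). None of 16 fatty acid synthesis genes was called, with a median of −0.11 (percentile 46.8), and Fasn, fatty acid synthase, was at −0.42.

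Lysosomal and matrix genes were higher at 10 µM. Of 31 lysosome and autophagy genes, 20 rose and 1 fell, Tfe3 (−0.62, named after its value was seen), with a median of 0.87 (percentile 100). Besides Hexa (2.27), the sialidase Neu1 (2.24) and the lysosomal proteases Ctsb (1.58) and Ctsa (1.53) rose. Of 42 extracellular matrix genes, 23 rose and 6 fell, with a median of 0.77 (percentile 100). The matricellular genes Thbs1, thrombospondin 1 (2.61), and Tnc, tenascin C (2.49), the membrane-bound metalloprotease Mmp14 (2.12) and Col12a1, a collagen (1.87), rose. Of 11 markers of fibroblasts and meninges, 5 of the listed genes being matrix genes as well, 4 rose and 3 fell. Their median was 0.06 and their mean −0.03 (percentile 80.1). Col1a2, a collagen I chain, rose from 1231 to 2406 FPKM (0.97) and the proteoglycan Dcn by 1.04, while S100a4, a calcium-binding protein of motile cells, fell from 2145 to 538.9 FPKM (−1.99) and the transcription factor Twist2 fell by 0.99.

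Interferon-inducible and MHC class I genes were also higher. Of 30 measured, 12 rose and 3 fell, with a median of 0.45 (percentile 99.8). B2m, the light chain of MHC class I, rose from 520.4 to 1573 FPKM (1.59). Xaf1 (2.08), the tethering factor Bst2 (1.74) and the GTPase Igtp (1.53) rose. Of 20 NF-kappaB targets and chemokines, 3 rose and 8 fell, with a median of −0.13 (percentile 32.0). The chemokine Cxcl12 rose from 64.5 to 443.5 FPKM (2.76), and Ptgs2, the inducible cyclooxygenase (−1.68), the cytokine signalling inhibitor Socs3 (−1.41) and the metalloprotease Mmp3 (−1.23, but −0.37 and not called with a pseudocount of 5 FPKM) fell. Histone genes listed as dependent on replication, and as a marker of RNA without poly(A) tails, had 9 of 19 members higher and 3 lower. Their median was 0.58 (percentile 99.7). The values do not show whether the RNA counted here carried such tails. Hist1h2bc (3.18), Hist1h4h (2.17), Hist1h1c (2.14) and Hist1h2ac, from 0.54 to 5.14 FPKM, rose. This list no longer stood apart without the lane 7 file of 10 µM (percentile 96.1), with no filter on low values (91.5) or with equal sums that leave out Snora62 (90.8).

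Of 14 heat shock genes, 7 fell and none rose, with a median of −0.60 (percentile 1.60). The mitochondrial chaperonin Hspd1 (−1.27), Hspa4l (−0.91), the HSP90 gene Hsp90ab1 (−0.85) and Hsph1 (−0.81) fell. By the mean over its members this list lay at the percentile 3.82. Of 23 NRF2 and oxidative stress genes, 9 fell and 4 rose, with a median of −0.47 (percentile 3.76, and 1.38 without the lane 7 file of 0 µM). The quinone reductase Nqo1 (−2.08), thioredoxin Txn1 (−1.59) and glutathione reductase Gsr (−1.49) fell, and the heme oxygenase Hmox1 rose from 183.0 to 807.1 FPKM (2.13). Of 33 ATF4 and unfolded protein genes, 5 rose and 9 fell, with a median of 0.04 and a mean of −0.01 (percentile 90.1). The ATF4 targets Trib3 (1.45), Chac1 (1.28) and Fgf21 (1.25, but 0.52 and not called with a pseudocount of 5 FPKM) rose, and Shmt2, of mitochondrial one-carbon metabolism, fell (−1.15).

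Lists of developmental pathways held changes in both directions and did not stand apart as reported. Of 22 YAP and SRF cytoskeletal targets, 4 rose and 2 fell, with a median of 0.19 (percentile 96.7), and Myl9, a myosin light chain (2.85), Tagln, transgelin (2.04), Acta2, smooth muscle actin (1.99), and Amotl2 (0.84) rose. This list stood apart by the mean over its members (99.8), with no filter on low values (97.96), at 5 FPKM or more (97.97) and without the lane 7 file of 10 µM (97.6). Of 17 TGF-beta, BMP and WNT targets, 5 rose and 4 fell, with a median of 0.06 (percentile 61.3). Id3, an inhibitor of differentiation factors (3.01), and Tgfb2 (1.92) rose, and Notum, a WNT deacylase (−1.76), and Skil (−1.35) fell. Of 11 NOTCH pathway genes, 3 rose and 4 fell, with a median of −0.17 (percentile 17.9): Notch3 (1.57) and Hes6 (1.27) rose, Hey1 (−1.65) and Lfng (−1.51) fell. Of 21 genes of epithelial and mesenchymal transition, 7 rose and 6 fell, with a median of −0.03 and a mean of 0.13 (percentile 72.6). Zeb1, a repressor of epithelial genes, rose by 2.02, and Spp1, osteopontin (−1.27), and Snai1 (−1.20) fell.

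Of 12 neural and glioma stem cell markers, 1 rose and 5 fell, with a median of −0.09 (percentile 45.2). The chromatin protein gene Hmga2 (−2.87), the intermediate filament gene Nes (−1.75) and the stem cell factor Sox2 (−1.21) fell, and Sox4 rose (1.64). Most markers of other brain cells lay below the level compared. Of 20 astrocyte markers, 8 were measured; 2 rose and 1 fell, with a median of −0.14 and a mean of 0.45 (percentile 31.5). Clu, clusterin (3.17), and Fgfr3 rose. Glul, glutamine synthetase (−0.64), fell, a call lost without the lane 7 file of 0 µM (−0.56) or the lane 6 file of 10 µM (−0.49), and under 4 other scalings, and Ndrg2 was at 0.48 (0.67 and called without the lane 7 file of 10 µM). By the mean over members the astrocyte list lay at the percentile 97.8. Of 20 microglia and macrophage markers, 5 were measured, with a median of 0.54 (percentile 91.4). Lyz2, lysozyme (1.59, from 0.09 to 2.30 FPKM, but 0.52 and not called with a pseudocount of 5 FPKM), and Tmem119 (0.98) rose. Cd14 was at −0.56 and Cd74 at 0.54; without the lane 6 file of 10 µM both were called, at −0.61 and 0.62. Too few members for a percentile were measured for oligodendrocytes, 2 with a median of 0.02 (Cnp and Pdgfra), for neurons, 3 with a median of −0.14, among them Stmn2, which fell (−1.01), and for endothelium and pericytes, 4 with a median of 0.09. None of the 5 genes that tell the sex of a culture reached the level compared.

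Besides Fmod and Pclaf, other genes outside the lists had some of the largest folds. Hmga1, a chromatin protein, fell from 712.4 to 45.6 FPKM (−3.94), and Il1rl1, the IL-33 receptor (−3.79), Prl2c2, a proliferin (−3.79), and Il18rap, an IL-18 receptor subunit (−3.70), fell. Plxdc1 (4.21), the integrin ligand Npnt (3.90), the small heat shock protein Cryab (3.52), the prostaglandin D synthase Ptgds (3.51), Cdsn (3.24), Sebox (3.18) and the matrix protein Ccdc80 (3.15) rose. Of the 30 lists tested, 4 stood apart as higher and 8 as lower at 10 µM. Lists of genes drawn independently would give 1.5, but genes of a list can move together, so 1.5 is no measure of chance here. With each file scaled to the same sum of FPKM without Snora62, the median of all genes moved from −0.03 to 0.17 and the share of called genes that were higher from 45.2% to 65.4%, so directions are relative to the scale of the files.

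The comparison of 5 with 0 µM asks how much of this is present at the lower dose. Most lists that stood apart at the higher dose also did so at the lower, in the same direction. Immediate early genes stood apart only at the higher dose and NRF2 genes only at the lower, and these differences were not tested. At 5 µM Fosl1 was at 3.89 FPKM (−3.69, −3.77 to −3.61), Ccnd1 at 137.8 FPKM (−0.78), Mki67 at 13.0 FPKM (−2.77) and Fmod at 80.3 FPKM (4.70). In all, 1771 genes were higher and 2107 lower, 30.9% of the genes compared. The lowest folds belonged to Fosl1, Hmga1 (−3.60), Prl2c2 (−3.46), Il18rap (−3.39) and Il1rl1 (−3.11). The highest belonged to Fmod, Plxdc1 (4.05), Npnt (3.95), Cryab (3.41) and Prelp, a matrix proteoglycan (3.28). Of the fixed genes, Etv5 (−1.32), Myc (−1.15), Spry4 (−0.77), Egr1 (−0.66) and Dusp6 (−0.63) fell. With equal sums that leave out Snora62, Egr1 (−0.48) was no longer called, nor was Spry4 with a pseudocount of 5 FPKM (−0.33). The call of Dusp6 was lost without the lane 6 file of 5 µM (−0.49) and under 3 other scalings.

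Of the 30 lists tested at 5 µM, 4 stood apart as higher and 8 as lower. All 38 G2 and M genes were lower (median −2.25), as were 35 of 36 S phase genes (−1.88), 25 of 29 genes of MYC and ribosome biogenesis (−1.10), 34 of 40 ribosomal protein genes (−0.75), 18 of 31 glycolysis and hypoxia genes (−0.89) and 13 of 21 ERK genes (−0.63). Heat shock genes had a median of −0.58 with 7 of 14 lower, and NRF2 genes of −0.47 with 8 of 23 lower and Hmox1 higher (1.95). The NRF2 list lay at the percentile 1.47 at 5 µM and 3.76 at 10 µM, and this difference was not tested; by the mean over members it was 3.99 at 5 µM. Matrix genes had a median of 0.88 with 26 of 42 higher, lysosome genes of 0.72 with 18 of 31 higher, interferon and MHC class I genes of 0.51 with 13 of 30 higher, and histones of 0.52 with 9 of 19 higher. The histone list no longer stood apart with a pseudocount of 5 (percentile 97.0), in the lane 7 files alone (95.3), against lists matched on length and GC content (97.1) or without the lane 6 file of 10 µM (93.0).

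Most genes called at 5 µM were called in the same direction at 10 µM. Of the called genes, 1572 were higher at both doses and 1945 lower at both, and 3 were called in opposite directions. Independent calls would share 279 and 402, but a shared control breaks that independence. Both comparisons use the same control library, which cannot be divided, so an unusual culture at 0 µM would give such an overlap too, and these counts cannot tell it from a shared response.

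**Figure D2:**
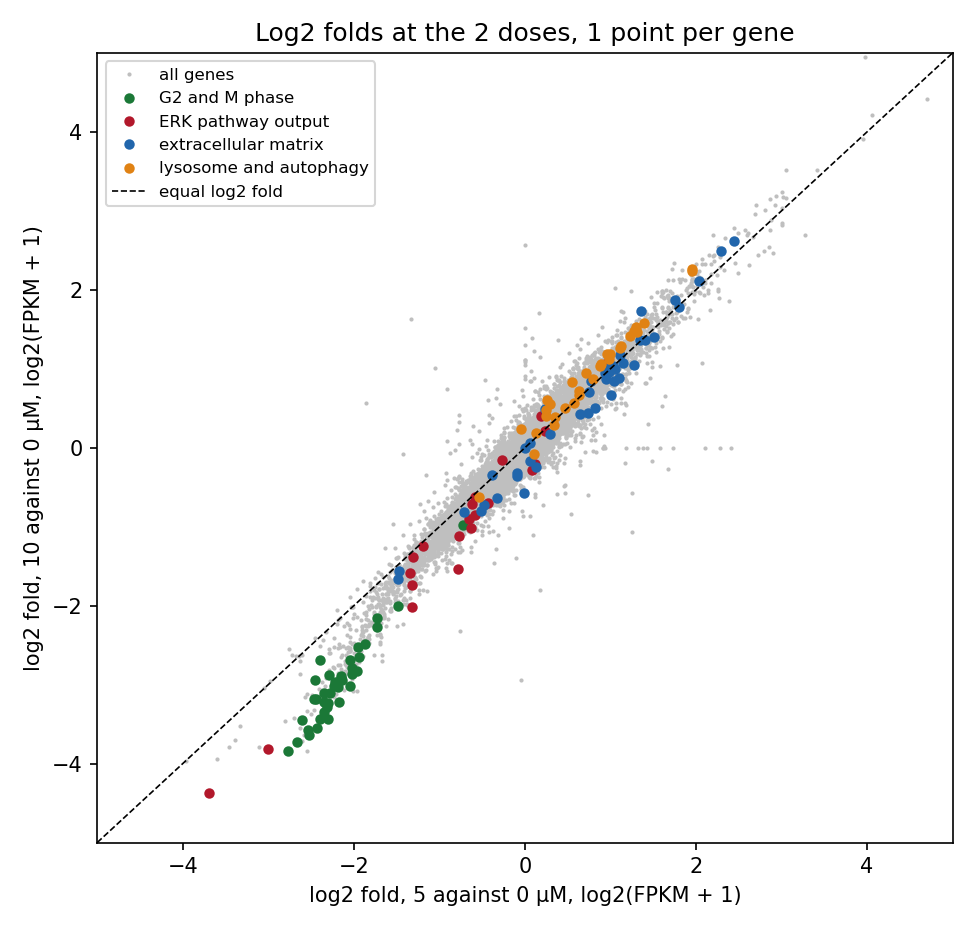
Log2 fold at 5 against 0 µM (horizontal) and at 10 against 0 µM (vertical) on log2(FPKM + 1), with 1 point per gene, members of 4 lists in colour and a dashed line of equal folds. Snora62, listed in 1 lane file only, lies beyond the axis. G2 and M genes fall below the dashed line (medians −2.25 at 5 µM and −3.02 at 10 µM), and matrix genes lie near it (0.88 and 0.77).

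The other 18 lists tested at 5 µM did not stand apart from random lists. Immediate early genes had a median of −0.26 (percentile 5.18), components from the PDGF receptor to RAS −0.01 with a mean of 0.05 (70.9) and other receptor tyrosine kinases −0.03 (54.4). Oxidative phosphorylation was at −0.31 (9.65, but 0.99 without matching on expression). CDK inhibitors and p53 targets were at 0.06 (85.4, but 98.6 without the lane 6 file of 5 µM and 98.7 by the mean), apoptosis regulators at −0.01 with a mean of 0.07 (63.3), ATF4 and unfolded protein genes at 0.10 (94.2) and NF-kappaB targets at −0.12 (27.7). Cholesterol synthesis was at −0.03 (70.4) and fatty acid synthesis at −0.03 (60.9). YAP and SRF targets were at 0.12 (92.6, by the mean 99.8), TGF-beta, BMP and WNT targets at 0.17 (86.3), NOTCH genes at 0.06 with a mean of −0.06 (59.6) and genes of epithelial and mesenchymal transition at 0.08 (89.3). Markers of stem cells were at −0.12 (36.4), of astrocytes at −0.03 with a mean of 0.44 (50.3, by the mean 97.8), of microglia at 0.64 (96.7, but 99.0 without the lane 7 file of 0 µM) and of fibroblasts at 0.20 (92.5, with no filter on low values 99.0).

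The comparison of 10 with 5 µM asks which genes differ between the treated libraries. With 1 library per dose, a difference between cultures cannot be told apart from the dose. Of 38 G2 and M genes, 31 were lower at 10 than at 5 µM, with a median log2 fold of −0.79 (percentile 0). Among them were Cdc20, an activator of the anaphase-promoting complex (−1.13, −1.20 to −1.06), the mitotic kinases Plk1 (−1.13) and Aurkb (−1.12), and Mki67 (−1.07). Of 36 S phase genes, 9 were lower, with a median of −0.41 (percentile 0). Pclaf, which is in neither list, fell by 1.29. Of 21 ERK genes, 4 were lower, with a median of −0.27 (percentile 0): Etv4 (−0.82), Ccnd1 (−0.75), Etv5 (−0.70) and Fosl1 (−0.68). In all, 52 genes were higher and 170 lower, 1.77% of the genes compared. Single lanes of 1 library differed by at least 1.5-fold for 1.19% of genes at 5 µM and 1.68% at 10 µM. That comparison averages no lanes and asks for no agreement in sign. Of the 170 lower genes, 40 belong to the cell-cycle lists, which hold 74 genes. Of the 170, 115 were also lower at 5 than at 0 µM and 29 were higher. Scaled to the same sum of FPKM, which Snora62 in the lane 6 file of 5 µM distorts, 687 genes were higher and 47 lower. The ERK median then became 0.10, with Ccnd1 (−0.34) and Etv5 (−0.40) no longer called, the S phase median −0.05 and the G2 and M median −0.44. Without Snora62 in the sum the counts were 69 and 164. The medians were then −0.24 for ERK genes, −0.38 for S phase and −0.77 for G2 and M.

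None of the matrix, lysosome, glycolysis or ribosomal genes of the lists was called between 5 and 10 µM. The ratio of the list median at 10 µM to that at 5 µM was 1.44 for ERK genes and 1.34 for G2 and M genes, against 1.02 for glycolysis and hypoxia and 0.883 for matrix genes. It was 1.29 for ribosomal proteins, 1.22 for lysosomes, 1.20 for S phase and 1.18 for ribosome biogenesis. The ERK medians are the values of single genes, Dusp6 at 5 µM and Egr1 at 10 µM. Their ratio thus sets different genes against each other. The mean log2 fold of ERK genes was −0.81 at 5 µM and −1.07 at 10 µM, and that of G2 and M genes −2.18 and −2.98. The order of the ERK and G2 and M ratios is therefore not firm. Small shared shifts still set some medians apart from random lists: ribosomal proteins at −0.18, ribosome biogenesis at −0.14 and fibroblast markers at −0.18 lay low, with S100a4 falling by 0.61, and lysosome genes at 0.16 lay high. Scaled to the same sum, which Snora62 distorts, these medians became 0.23, 0.25, 0.21 and 0.56, with the median of all genes at 0.35. With Snora62 left out of the sum they were −0.14, −0.11, −0.15 and 0.19. Among the scalings, a change of sign was thus seen only with Snora62 in the sum. Lists of immediate early genes (−0.10, percentile 0.920), interferon and MHC class I (−0.11, 0.310) and NF-kappaB (−0.10, 1.54) lay low and cholesterol synthesis (0.03, 98.6) high, and each of these ended without 1 lane file. Without the lane 6 file of 10 µM the percentiles were 8.74, 2.93 and 5.35, and without the lane 6 file of 5 µM they were 2.70 for interferon and 3.16 for NF-kappaB; without the lane 7 file of 5 µM cholesterol synthesis lay at 97.48.

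Among single genes, Abca1, a cholesterol exporter, was at 6.83, 17.6 and 30.1 FPKM at 0, 5 and 10 µM (0.74 from 5 to 10 µM). Hotairm1, a long noncoding RNA, was at 17.8, 17.4 and 30.4 FPKM (0.77, but 0.54 and not called in the lane 7 files alone). Mrm1, a mitochondrial RNA methyltransferase, was at 6.23, 22.0 and 4.98 FPKM and so was lower at 10 than at 5 µM (−1.94). Further calls rest on lanes that differ. Zeb1 rose by 0.97 from 5 to 10 µM, but its lanes read 59.7 and 31.6 FPKM at 5 µM and 69.6 and 107.3 FPKM at 10 µM, and the fold was 0.53 without the lane 7 file of 5 µM. Ccdc191 was called at 0.84, and at 0.15 it was not called without the lane 7 file of 10 µM. By contrast, the pseudogene Rps13-ps1 was called at 2.42 (2.12 to 2.71) with similar lanes. They read 2.52 and 1.82 FPKM at 5 µM and 17.5 and 14.3 FPKM at 10 µM. Its lanes at 0 µM, which take no part in this comparison, read 32.5 and 2.88 FPKM. Of the 52 higher genes, 14 remained among protein-coding genes alone, and the count was 99 without the lane 6 file and 109 without the lane 7 file of 10 µM.

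Of the 1978 genes higher at 10 than at 0 µM, 1383 (69.9%) had their 5 µM value between the other two, and of the 2396 lower genes 2015 (84.1%) did. The median ratio of the log2 fold at 5 µM to the log2 fold at 10 µM was 0.916 for higher and 0.855 for lower genes. The step from 5 to 10 µM passed the size rule in the same direction for 37 of the higher and 134 of the lower genes, and in the opposite direction for 5 and 0. The genes were picked by their difference between 0 and 10 µM, so only the 5 µM value is free, and chance has no fixed share here.

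**Figure D3:**
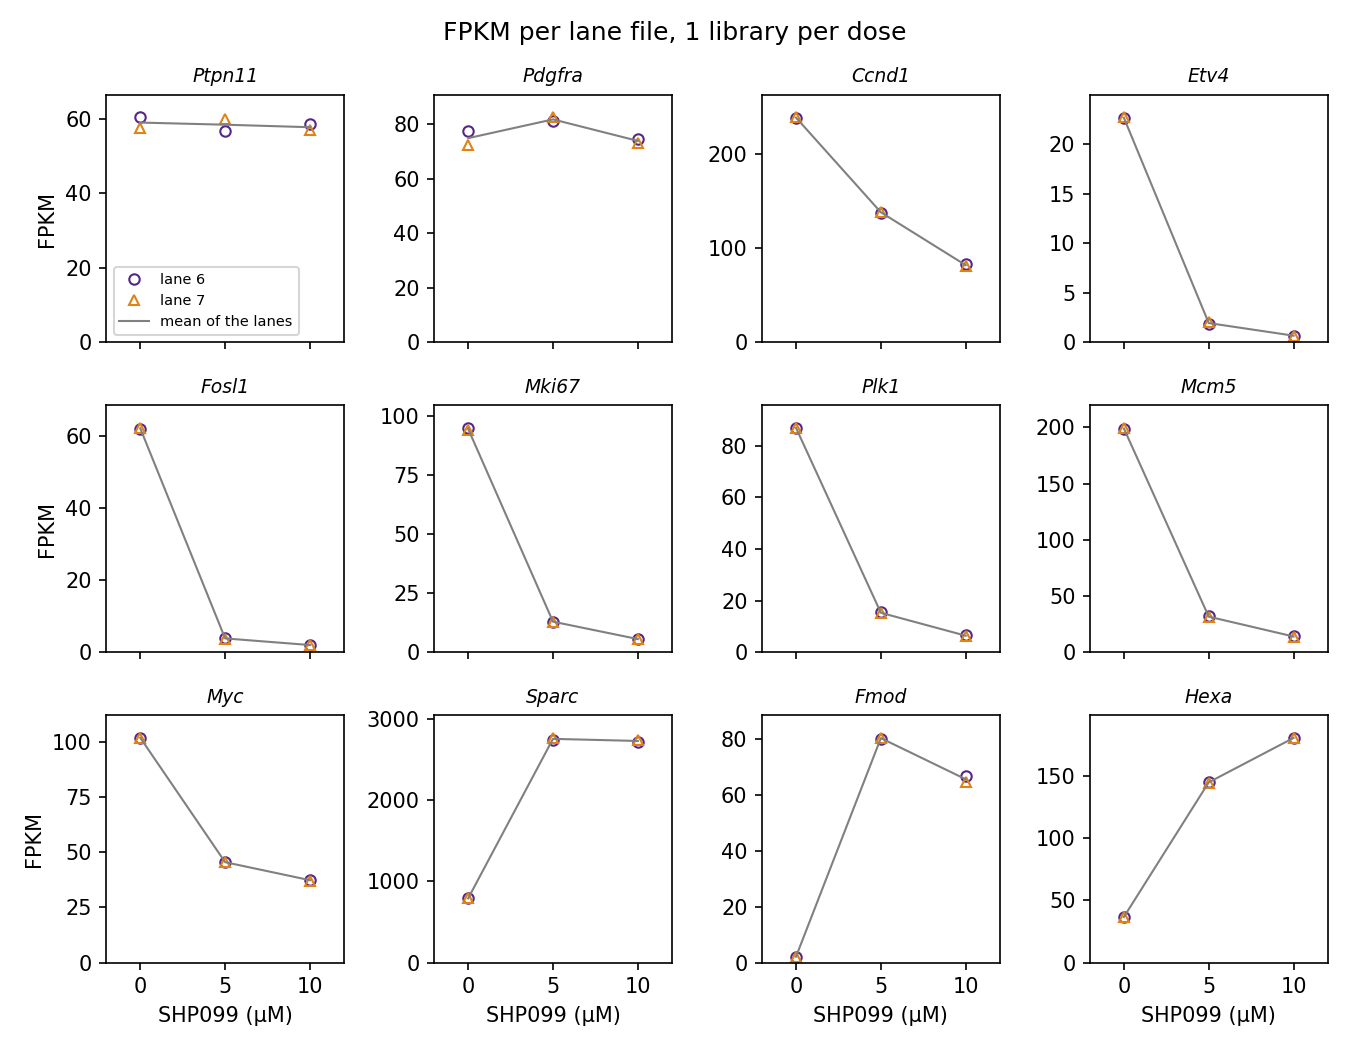
FPKM of 12 genes per lane file at 0, 5 and 10 µM SHP099, with circles for lane 6, triangles for lane 7 and a grey line through the means; each axis starts at 0 and each dose is 1 library. Means of Ptpn11 lay between 57.7 and 59.0 FPKM, Ccnd1 fell from 238.0 to 137.8 and 81.8 FPKM, and Fmod rose from 2.12 to 80.3 and 65.6 FPKM.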

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

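The alternatives with protein-coding genes alone, with equal sums without Snora62 and with random lists matched on length and GC content were chosen after seeing the data. The 18 leading list results (ERK, S phase, G2 and M and others, at 5 and at 10 against 0 µM) kept their side of the percentile limits and their direction in all 396 alternative values. The lists called leading were chosen by hand, so this record does not describe every list that stood apart. Heat shock, histone, NRF2 and immediate early genes also stood apart at 5 or 10 µM but are not among them. Each of these lost that place under at least 1 alternative. Of the 212 alternative values of the 10 counts, 174 stayed within 1.5 times the reported count and 38 did not. Of 187 values of named genes, 146 kept call and direction under every alternative and 41 changed call under at least 1. In the 72 other list results, 1502 alternative values were alike, 46 stood apart newly, 32 no longer, and 1 reversed: the astrocyte list at 10 against 0 µM, at the percentile 97.77 by the mean over members. These labels follow the percentile, not the sign of the median. Scaled to the same sum, which Snora62 distorts, the medians at 10 against 5 µM changed sign for some lists. They went from −0.27 to 0.10 for ERK genes and from −0.18 to 0.23 for ribosomal proteins. Both still counted as alike. With Snora62 left out of the sum these medians were −0.24 and −0.14.

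The 2-fold rule asks for more by construction. It gave 652 higher and 755 lower genes at 5 µM, 733 and 995 at 10 µM, and 15 and 28 for 10 against 5 µM; 558 and 710 were shared, and 524 and 920 had 5 µM in between. A pseudocount of 5 FPKM, which shrinks folds of low genes by construction, gave 927 higher genes at 5 µM, 1029 at 10 µM, 826 shared and 723 with 5 µM in between, and 10 higher and 38 lower for 10 against 5 µM; a pseudocount of 0.1 gave 116 and 309 there.

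Scaling to the same sum moved the median of all genes to −0.19 (5 against 0 µM), 0.17 (10 against 0 µM) and 0.35 (10 against 5 µM), with Snora62 taking 40.5% of the sum of the lane 6 file of 5 µM. It gave 3020 higher genes at 10 against 0 µM, 2913 and 358 with 5 µM in between, and 687 higher and 47 lower for 10 against 5 µM. The share of called genes that were higher was 28.8%, 65.4% and 93.6%, against 45.7%, 45.2% and 23.4% as reported. Without Snora62 the medians were 0.14, 0.17 and 0.02 and the shares 65.2%, 65.4% and 29.6%; 3032 genes were higher at 10 µM, 2425 and 1294 were shared, and 2298 and 1336 had 5 µM in between.

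For 10 against 5 µM, leaving out 1 lane file gave 51 to 109 higher genes, and lane 6 alone gave 123 and 271, lane 7 alone 135 and 260. With fewer files, fewer lane pairs must match and folds are averaged over fewer lanes, and these effects were not told apart. There, 15 genes were higher at 5 FPKM or more and 14 among protein-coding genes, with 10.3% and 9.21% of called genes higher; limma over the lanes gave 21 and, with the lane as a block, 19. Where no construction is named, the cause was not tested. Planned folds and an edgeR run on recovered fragments were not run, since whole fragments came out only for genes with 1 annotated transcript. At 1 FPKM the counting error of a 2 kb transcript is 10.3% to 12.7% per lane; whether depth limits the calls there was not tested.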

Other observations

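Of the listed markers, 8 of 20 of astrocytes, 2 of 21 of oligodendrocytes and 3 of 21 of neurons reached a mean of 1 FPKM at any dose. Gfap, the intermediate filament of astrocytes, was at 0.03, 0.02 and 0 FPKM at 0, 5 and 10 µM, while Vim, vimentin, was at 1358, 1816 and 1625 FPKM. The oligodendrocyte factor Olig2 and the water channel Aqp4 were listed at 0 in all 6 files. Genes listed as markers of microglia and macrophages or of endothelium and pericytes varied in level. The leukocyte gene Ptprc reached at most 0.04 FPKM and the endothelial gene Pecam1 0.15 FPKM. Eng, listed for endothelium and pericytes, was at 34.9, 42.1 and 40.9 FPKM. Tmem119, listed for microglia and macrophages, was at 63.9, 119.0 and 127.0 FPKM. These genes and the following were chosen after their values were seen.

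The long noncoding RNA Malat1 was at 273.8, 424.2 and 605.4 FPKM and Neat1 at 287.8, 460.1 and 526.0 FPKM. Of 33 histone genes compared, 17 were higher at 10 than at 0 µM and 7 lower, while S phase genes were lower. Rpph1, the RNA of RNase P, was at 6.39, 2.77 and 3.51 FPKM, and Rmrp varied between lanes of the same library, with 6.61 and 4.29 FPKM at 0 µM. Snora62 was listed at 385860 FPKM in 1 of the 6 files and at 0 in the other lane of the same library.

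All tests below were chosen after the results were seen, although all scalings but the one without Snora62 had been fixed as alternatives before. The lower level of S phase and G2 and M genes was set against 3 explanations. For the scaling of FPKM between libraries, the G2 and M median at 10 against 0 µM nearest to 0 over the 4 other scalings was −2.82. None of these scalings accounts for the lower level. They moved the median of all genes only from −0.03 to at most 0.17, so they could not have removed a median of −3.02. The outcome was thus fixed in advance, and nothing further is drawn from it. Transcript length or GC content is argued against: the 2.5th percentile of matched random lists was −0.36, far above the median of −3.02. A difference between the cultures other than the inhibitor, such as density or time in culture, or an unusual culture at 0 µM, cannot be told apart from the dose, because there is 1 library per dose, and the median of −0.79 between 5 and 10 µM does not settle it. A hypothesis is that the inhibitor lowered the share of dividing cells with dose, which repeated cultures could test.

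The lower level of ribosomal protein genes, with a median of −0.97, could come from their short transcripts or from reads placed on pseudogenes. Random lists matched on expression, length and GC content reached −0.56 at their 2.5th percentile, which argues against the bias as the whole source. The summed FPKM of 288 ribosomal protein pseudogenes, those marked by -ps in their names, went from 104.4 at 0 µM to 72.8 at 10 µM. This change of −31.6, beside −27617 for the 40 listed genes, shows no reads moving to these pseudogenes. Pseudogenes under other names were not summed, so reads placed there are left open. A difference between cultures stays open.

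The higher level of extracellular matrix genes, with a median of 0.77 at 10 µM, might reflect fibroblasts in the culture, and the values leave this open. The fibroblast markers Lum, Dpt, Thy1 and Fap, chosen after their values were seen, reached at most 0.57 FPKM at 5 and 10 µM, but that highest value is of Lum, which was at 0.08 FPKM at 0 µM. Of 11 fibroblast and meningeal markers compared, 4 were higher and 3 lower, with a median of 0.06: Dcn and Col1a2, which are matrix genes themselves, rose by 1.04 and 0.97, and S100a4 (−1.99) and Twist2 (−0.99) fell. A difference between the cultures other than the inhibitor could also account for the rise, and with 1 library per dose it cannot be told apart from a response to SHP099.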
